A study of Mus musculus with 4 samples.

How the data were processed

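Total RNA of 4 mouse gastric organoid libraries was sequenced from libraries made with the Illumina TruSeq Stranded Total RNA Gold kit, per the labels' protocols. The kit removes ribosomal RNA and keeps the strand. The 2 control libraries (Cdh1 and Trp53 knockout) and the 2 Smad4 knockout libraries (Cdh1, Trp53 and Smad4 knockout) were assigned from the genotype label, and replicate numbers follow the order of the samples, so they pair nothing. The columns of Control 2 carry that sample's title with an added 2, and were taken as that sample because its file holds no other; whether they come from a repeat run is not given in the sources used here. The submitters' processing notes name bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0, StringTie 2.1.3b and the mm10 build. The strand setting, read filters and counting step are not given in the sources used here.

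Per the file headers, the deposited files give a read count, an FPKM and a TPM value per gene for 45777 genes with RefSeq gene IDs. The deposited counts are whole numbers and were treated as estimated counts. In 30 to 42 short single-transcript genes per library they were proportional to the deposited FPKM times gene length within 1%. FPKM is defined from count and length, so this check cannot tell counted from estimated reads. The deposited FPKM were used for that check only, and the deposited TPM for an alternative test. A total of 1 further FPKM column, found in the file of another sample and identical to that sample's own column at all 45777 genes, was not used. Spreadsheet dates had replaced 26 gene symbols, and all 26 were restored from the gene ID. Coordinates come from the RefSeq annotation of GRCm38, which held 45679 of the gene IDs, and 511 of 514 listed gene names matched a gene in the files.

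Depth ranged from 85649781 to 96402585 counts in the knockouts and from 92334224 to 99845702 in the controls, and a count of 0 allows up to 3 counts in a library. Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM normalization, filterByExpr with its minimum count of 10) in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment over 18115 genes, at an adjusted p of 0.05. The common dispersion was 0.0680, a coefficient of variation of 26.1%. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so none was used. CPM values use the TMM-scaled library sizes.

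Before the data were examined, 34 gene lists, the tests and the rule for named genes were fixed. The rule names Smad4, Cdh1 and Trp53, then the called genes with the largest changes and up to 4 called members per called list. As no gene was called, it gave the 5 genes per direction with the smallest p, among genes with a mean of at least 5 CPM in the higher group whose groups do not overlap, without predicted genes, pseudogenes and small noncoding RNA. Up to 4 members of each called list, other members that go against their list, and further genes with values outside this rule were named after their values were seen. Some members that count in the list tests and totals are not reported here by name. For marker lists of other cell types the rule gave the members with the highest level. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the 30 lists with at least 4 tested genes), and again with the correlation estimated from the data, which rests on 2 residual degrees of freedom. Lists overlap, as with Smad7 in the SMAD family, TGF-beta and BMP lists and Ccn2 in the TGF-beta and YAP lists.

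The alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma with trend on log2(TPM + 1) for genes with a TPM of at least 1 in at least 2 libraries, a minimum of 2-fold, fry, leaving out mitochondrial, ribosomal protein and histone genes, and leaving out each library in turn. Alternatives planned for files without counts did not apply. Protein-coding genes only, robust moderation, list tests without mitochondrial, ribosomal protein and histone genes, and the SMAD family list without Smad4 were added after seeing the data.

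The tests were tried on simulated data with the means and library sizes of these libraries, and with dispersions scattered around their trend. Each of the 5 gene simulations held 200 changed genes. Over the 5 simulations edgeR recovered 4.6% of genes changed 2-fold and 64.2% of genes changed 4-fold with 3.2 false calls per simulation, and DESeq2 recovered 62.0% and 90.4% with 152.2. An earlier version of the simulation drew no scatter of the dispersion between genes and recovered more genes with edgeR. The scatter, with the prior degrees of freedom of 3.93 found in these data, was added after that result was seen. That 3.93 comes from edgeR's quasi-likelihood step and was applied to the count dispersion. The scatter is skewed, so the simulated dispersions lay above the trend on average. The rates of false calls and of recovery depend on this setting. In 20 simulations with independent genes, camera called 4 of 600 unchanged list tests, and called the TGF-beta list moved by 1.5-fold in 20 of 20.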

Results

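RNA sequencing was used to compare mouse gastric organoids labelled as knockouts of Cdh1 and Trp53, called control organoids here after the genotype label, with organoids labelled as knockouts of Cdh1, Trp53 and Smad4. Gastric organoids are stomach epithelial cells grown as small hollow structures in a gel. Cdh1 encodes the adhesion protein E-cadherin, Trp53 encodes the tumour suppressor p53, and Smad4 encodes the shared partner of the SMAD proteins that carry TGF-beta and BMP signals to the nucleus. Each genotype was represented by 2 libraries, and each of the 4 libraries came from a separately named organoid line. The titles of the 4 samples begin with the same stem, so the lines may not be independent. Before harvest the cells spent 2 days in medium with B27 and N2, without serum and without conditioned medium. The labels do not say whether the lines came from separate animals, or whether the Smad4 knockout lines were derived from the control lines. Gene p-values therefore measure the spread between these 4 libraries only. List p-values from a preset correlation compare list members with other genes, and rest less on that spread. The total count was 99845702 and 92334224 in Control 1 and 2, and 85649781 and 96402585 in Smad4 Knockout 1 and 2. Between 20586 and 20999 genes had a count above 0 in a library, and protein-coding genes took from 92.95% to 93.98% of the counts.

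The first question was whether the targeted genes followed the labels. Smad4 (gene ID 17128, chromosome 18, 73634790 to 73703791 in GRCm38, the build also called mm10) was at 94.5 and 103 CPM in the control libraries, where CPM is the count scaled to the size of the library. It was at 54.4 and 52.9 CPM in the knockout libraries, a level of 54.2% of the control level. The group means were 98.9 ± 6.21 CPM (SD, n = 2) and 53.7 ± 1.05 CPM (SD, n = 2), and the log2 fold change was -0.88 (SE 0.10). Adjusted over the SMAD family list alone, Smad4 fell (edgeR adjusted p = 0.00114), and over all 18115 genes tested its adjusted p was 0.677. Smad4 transcript thus remained in both knockout libraries; an edited gene can still be transcribed.

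Cdh1 and Trp53, named as knocked out in both genotypes, did not pass the test between them. Cdh1 (gene ID 12550, chromosome 8, 106603350 to 106670247) was at 30.7 and 26.02 CPM in the controls and at 30.6 and 44.1 CPM in the Smad4 knockouts (edgeR adjusted p = 0.832). Trp53 (gene ID 22059, chromosome 11, 69580348 to 69591873) was at 4.87 and 6.98 CPM in the controls and at 5.43 and 4.69 CPM in the Smad4 knockouts (edgeR adjusted p = 0.963). No library with intact Cdh1 or Trp53 was analysed here, so these values do not check the knockout of either gene.

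**Figure D1:**
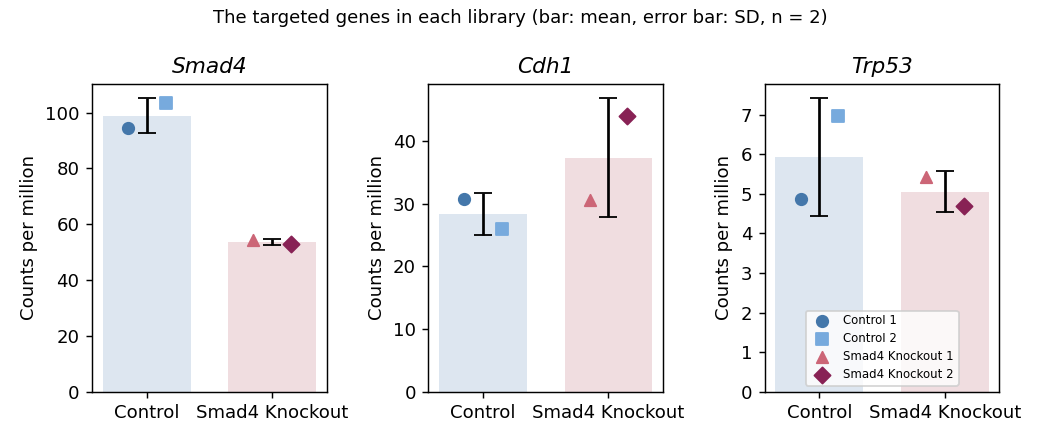
CPM of Smad4, Cdh1 and Trp53 in each of the 4 libraries, with bars for the group mean and error bars for the SD (n = 2). Smad4 lies at 54.4 and 52.9 CPM in the knockout libraries, below 94.5 and 103 CPM in the controls, while the groups overlap for Cdh1 and for Trp53.

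The main question was which genes differ with the Smad4 knockout on the Cdh1 and Trp53 knockout background. Among genes higher in the Smad4 knockouts, the smallest p-values belonged to Ceacam2, Muc13, Itpr2, Sptssb and Clca3b. Muc13, a transmembrane mucin, was at 0.459 and 0.475 CPM in the controls and at 5.99 and 17.9 CPM in the knockouts (log2 fold change 4.67, SE 0.58). Itpr2, an intracellular calcium channel, was at 19.1 and 17.4 CPM against 35.4 and 36.3 CPM (log2 fold change 0.98, SE 0.12). Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, was at 11.8 and 8.82 CPM against 28.1 and 37.0 CPM (log2 fold change 1.66, SE 0.21). Ceacam2 (log2 fold change 2.46, SE 0.30) and Clca3b (1.06, SE 0.14) have close relatives in the genome, so their counts are uncertain where reads were shared. Among genes lower in the knockouts, the smallest p-values belonged to Smad4, Rhob, Dusp5, Procr and Prss22. Rhob, a small GTPase, was at 55.9 and 56.3 CPM against 38.3 and 34.6 CPM (log2 fold change -0.62, SE 0.11). Dusp5, a phosphatase of ERK, was at 52.8 and 45.2 CPM against 32.0 and 28.6 CPM (-0.69, SE 0.13). Procr, the endothelial protein C receptor, was at 17.4 and 17.6 CPM against 10.7 and 8.86 CPM (-0.84, SE 0.16), and Prss22, a serine protease, had a log2 fold change of -0.78 (SE 0.15).

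None of these genes passed edgeR's test over all genes, and each of them had an edgeR adjusted p of 0.677, while all of them were among the DESeq2 calls given below. With edgeR's quasi-likelihood test, 0 genes were higher and 0 were lower among 18115 tested, while 603 higher and 550 lower genes had an unadjusted p under 0.05, against 906 in all that chance alone would give. With Control 1 and Smad4 Knockout 2 set against Control 2 and Smad4 Knockout 1, a grouping that mixes the genotypes, 1463 genes had an unadjusted p under 0.05, more than the 1153 of the real grouping, and the other mixed grouping gave 278. DESeq2 called 99 genes higher and 34 lower, and limma on TPM called 0 of 13277. In 117 of the DESeq2 calls Smad4 Knockout 2 lay further from the controls than Smad4 Knockout 1. Simulated data held 200 changed genes, with means and a dispersion trend from these libraries, and with dispersions that lay above that trend on average. DESeq2 made on average 152.2 false calls there, and edgeR 3.2. DESeq2 thus made many false calls in simulation, but changed genes loosen the adjusted threshold. The 152.2 is therefore not the number expected where no gene changes, and how many DESeq2 calls are false here was not tested. In the same simulated data edgeR found 4.6% of genes changed 2-fold and 64.2% of genes changed 4-fold. Without Smad4 Knockout 1, edgeR called 48 genes higher and 44 lower, and without Control 1 it called 1 gene higher, Fcgbp, which was named after its value was seen. Fcgbp was at 71.7 and 14.4 CPM in the controls and at 145 CPM in each knockout library.

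The libraries did not group by genotype. The root mean square distance on the log2 scale, over 10804 genes with a mean of at least 5 CPM, was 0.30 between the controls and 0.290 between the knockouts. Smad4 Knockout 1 was closer to Control 2 (0.244) and to Control 1 (0.272) than to Smad4 Knockout 2, and both controls were closer to it than to each other. Smad4 Knockout 2 was closer to Smad4 Knockout 1 than to Control 1 (0.355) or Control 2 (0.421). The 2 control libraries and the 2 knockout libraries did not overlap for 36.9% of the tested genes, where chance gives 33.3%. Mitochondrial genes took 0.94% and 1.18% of the counts in the controls and 0.95% and 1.48% in the knockouts. Ribosomal RNA took 0.242% and 0.389% in the controls and 0.243% and 0.562% in the knockouts, so both shares were highest in Smad4 Knockout 2.

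Gene lists fixed before the data were examined were then tested with camera, which asks whether the members of a list lie higher or lower than the other genes. Among 30 lists with at least 4 tested members, 8 were higher and 5 were lower in the Smad4 knockouts with the preset correlation of 0.01. With the correlation estimated from the data camera called 0 lists, with 0 at an unadjusted p under 0.05 against 17 with the preset, and fry called 0, with 1 at an unadjusted p under 0.05. The smallest adjusted p among lower lists belonged to target genes of TGF-beta and SMAD proteins, and among higher lists to intestinal markers. The estimated correlation was 0.455 in that TGF-beta list and 0.551 in the intestinal list, far above the preset. Over the called lists it ranged from -0.024, in the mucous neck list, to 0.551. Where members vary together, p-values from the preset are too small. That does not account for every lost call, since the mucous neck list (-0.024) and the squamous list (0.028) lost theirs too. Camera with an estimated correlation rests on 2 residual degrees of freedom here, so it can hardly call any list. Its adjusted p of 0.551 is shared by all 13 called lists and tells none of them apart. No member of any list passed over all genes in edgeR, so the members named from here on were chosen after their values were seen. They are members with small p in the direction of their list, members that go against it and some other members of interest. Of 70 single genes followed when a library was left out, the log2 fold change of 33 moved by over 1.5 times without Smad4 Knockout 2, and that of 41 without at least 1 of the libraries.

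The TGF-beta SMAD target list was lower in the Smad4 knockouts, with 18 of its 20 members lower and 13 of them lower in both knockout libraries than in both controls. The median log2 fold change of the list was -0.37, and camera gave adjusted p = 9.0e-09, against adjusted p = 0.551 with an estimated correlation. Pmepa1, a feedback inhibitor of TGF-beta signalling, was at 118 and 112 CPM in the controls and at 86.1 and 55.5 CPM in the knockouts (log2 fold change -0.70, SE 0.21, and -0.40 without Smad4 Knockout 2). Ltbp2, a latent TGF-beta binding protein, was at 4.48 and 4.02 CPM against 1.64 and 0.774 CPM (-1.82, SE 0.40), and Tgif1, a transcriptional corepressor, had a log2 fold change of -0.38 (SE 0.11). Tsc22d1 (0.14) and Tgfbi (1.23, with at most 0.41 CPM in any library) were the members above 0. Adjusted over the list alone, 0 members passed, and over all genes 0 passed in edgeR and 2 in DESeq2, with Ltbp2 among them. With the preset correlation the list was also called after any of the 4 libraries was left out, and without Smad4 Knockout 2 its median was -0.21 (adjusted p = 0.000743). Both groupings that mix the genotypes also called this list (camera adjusted p = 0.0117 and 0.0475). They are not free of a genotype difference that is larger in 1 knockout library, and this list lay at -0.21 in Smad4 Knockout 1 and -0.47 in Smad4 Knockout 2.

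The list of intestinal and intestinal metaplasia markers was higher in the knockouts, with 11 of 12 tested members higher and a median log2 fold change of 1.09. Camera gave adjusted p = 1.5e-08, against adjusted p = 0.551 with an estimated correlation. Cdh17, an intestinal cadherin, was at 29.2 and 15.6 CPM in the controls and at 73.2 and 113 CPM in the knockouts (log2 fold change 2.06, SE 0.35). Hnf4g, an intestinal transcription factor, was at 2.51 and 2.81 CPM against 5.02 and 8.21 CPM (1.32, SE 0.30), and Tff3, a goblet cell peptide, was at 0.949 and 0.259 CPM against 3.05 and 8.95 CPM (3.31, SE 0.76). Adjusted over the list alone, Cdh17, Hnf4g and Tff3 rose, which is 3 members in edgeR against 0 over all genes, where DESeq2 called these 3 and Lgals4. Lgals4, at 260 and 170 CPM against 305 and 483 CPM (0.87, SE 0.28), and Clca1, a goblet cell protein at 184 and 63.02 CPM against 291 and 345 CPM (1.36, SE 0.46), did not pass over the list alone in edgeR. The log2 fold change of Lgals4 was 0.52 without Smad4 Knockout 2. Cdx2, a regulator of intestinal identity, was at 24.7 and 19.02 CPM against 25.9 and 37.4 CPM, and Krt20 was the member below 0, at -0.24. Fabp1 and Guca2a had 0 counts in all libraries. The controls themselves differed in this list, with a median of -0.76 for Control 2 minus Control 1. With the preset correlation the list was also called after any of the 4 libraries was left out, and its median was 0.56 without Smad4 Knockout 2 (adjusted p = 0.000743) and 0.60 without Control 2. The grouping of Control 1 with Smad4 Knockout 2 also called it (adjusted p = 0.00403).

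**Figure D2:**
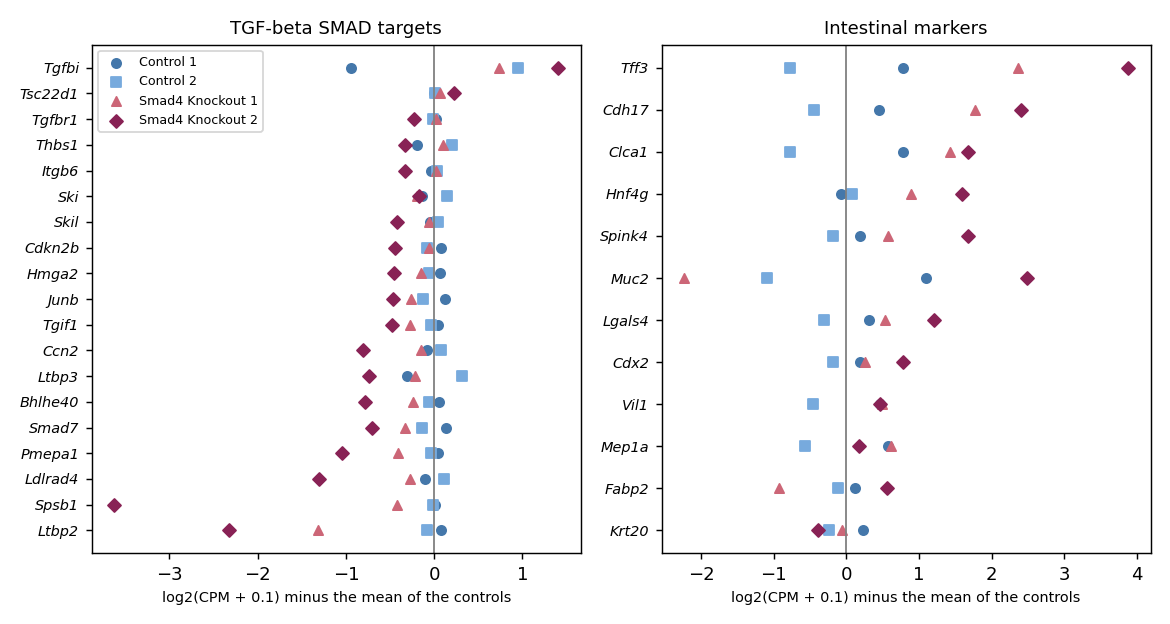
Log2(CPM + 0.1) of 19 of the 20 tested members of the TGF-beta SMAD target list and of each tested member of the intestinal list in the 4 libraries, minus the mean of the 2 controls. For most TGF-beta targets Smad4 Knockout 2 lies furthest to the left, as for Pmepa1 at 55.5 CPM, and for Cdh17 both knockouts, at 73.2 and 113 CPM, lie to the right of both controls.

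Lists of extracellular matrix and YAP target genes were lower as well. Of the collagens and basement membrane list 13 of 17 tested members were lower, with a median log2 fold change of -0.29 (camera adjusted p = 2.9e-04, and adjusted p = 0.551 with an estimated correlation). Col5a1 was at 5.99 and 5.91 CPM in the controls against 3.03 and 2.22 CPM in the knockouts (log2 fold change -1.18, SE 0.25). Col7a1, the anchoring fibril collagen, was at 17.9 and 17.8 CPM against 10.6 and 4.798 CPM (-1.22, SE 0.36), and Lamb1, a laminin chain, was at 335 and 349 CPM against 283 and 223 CPM (-0.43, SE 0.14). Without Smad4 Knockout 2 the log2 fold changes of Col7a1 and Lamb1 were -0.74 and -0.26, and without Smad4 Knockout 1 that of Col7a1 was -1.90. Col1a1 (-1.15, and from -1.48 to -0.70 over the libraries left out) and Col3a1 (-2.34, and from -7.83 to -1.33) were at most at 1.53 CPM. Both are also in the fibroblast list, whose 3 tested members were all lower in both knockouts than in both controls. Of the YAP and TEAD target list 13 of 16 members were lower, with a median of -0.21 (camera adjusted p = 2.9e-04, and adjusted p = 0.551 with an estimated correlation). Ccn1 was at 167 and 134 CPM against 113 and 92.9 CPM (-0.55, SE 0.16), and Ankrd1 was at 245 and 154 CPM against 136 and 107 CPM (-0.71, SE 0.24, and -0.33 without Control 1). Axl, a receptor tyrosine kinase, was at 184 and 176 CPM against 130 and 56.2 CPM (-0.95, SE 0.36). Its log2 fold change was -0.46 without Smad4 Knockout 2 and -1.68 without Smad4 Knockout 1. Adjusted over the list alone, 0 members of either list passed in edgeR, and over all genes DESeq2 called 1 collagen list member, Col7a1. Without Smad4 Knockout 2 neither list was called (collagen median -0.26, adjusted p = 0.0900, and YAP median -0.06, adjusted p = 0.104), and without Control 2 the collagen list was not called either (median -0.04, adjusted p = 0.119). The collagen median was -0.53 without Control 1 or without Smad4 Knockout 1, and the YAP median -0.38 without Smad4 Knockout 1.

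The SMAD family list and the list of chemokines, cytokines and NF-kB targets were the other lists called lower. The SMAD family list (4 of 7 tested members lower, median -0.06, camera adjusted p = 0.00574, and adjusted p = 0.551 with an estimated correlation) holds Smad4 itself. After Smad4 was taken out of it, a test chosen after seeing the data, its adjusted p was 0.341. Smad4 was its 1 member that passed adjusted over the list alone. Smad7, the inhibitory SMAD, was at 21.7 and 17.9 CPM against 15.7 and 12.02 CPM, and Smad2 and Smad3 had log2 fold changes of -0.06 and -0.28, with -0.12 for Smad3 without Smad4 Knockout 2. This list was not called without Control 2 (median -0.12, adjusted p = 0.0574) or without Smad4 Knockout 2 (median -0.02, adjusted p = 0.183). The chemokine list had 13 of 20 tested members lower and a median of -0.16 (camera adjusted p = 0.0486, and adjusted p = 0.551 with an estimated correlation). Csf2, a growth factor for myeloid cells, was at 11.3 and 9.45 CPM against 6.28 and 3.45 CPM (-1.09, SE 0.31, and -0.71 without Smad4 Knockout 2), Csf3 had a log2 fold change of -0.65 (SE 0.22, and -0.38 without Smad4 Knockout 2), and Il1a was at 145 and 90.8 CPM against 78.9 and 43.7 CPM. Cxcl1 and Il18, also members, were above 0 at 1.51 and 0.74. Cxcl1 was at 4.9 and 3.05 CPM against 6.77 and 15.9 CPM, highest in Smad4 Knockout 2. In edgeR 0 members passed adjusted over the list alone, and over all genes DESeq2 called 1, Cxcl1, as higher. This list was not called without Control 1 (median -0.02, adjusted p = 0.814), without Smad4 Knockout 1 (adjusted p = 0.270) or without Smad4 Knockout 2 (adjusted p = 0.183), and its median was -0.28 without Control 2.

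Markers of gastric mucous neck cells and of spasmolytic polypeptide-expressing metaplasia were higher as a list, though its members were split, with 6 higher and 5 lower. The median log2 fold change of its 11 members was 0.63 and the mean 0.01, since Muc6 was at 0.16 and 0.13 CPM in the controls and at 0 counts in both knockouts (camera adjusted p = 0.00574, and adjusted p = 0.551 with an estimated correlation). Adjusted over the list alone, Dmbt1, Cftr, Tff2 and Agr2 rose and Muc6 fell, which is 5 members in edgeR against 0 over all genes, where DESeq2 called 3, Dmbt1, Tff2 and Agr2. Dmbt1, a secreted mucosal glycoprotein, was at 44.5 and 27.9 CPM in the controls and at 84.7 and 97.8 CPM in the knockouts (log2 fold change 1.33, SE 0.23). Tff2, the spasmolytic polypeptide, was at 17.9 and 12.9 CPM against 37.7 and 23.4 CPM (0.99, SE 0.27). Without Smad4 Knockout 1 the log2 fold change of Tff2 was 0.60. Cftr, a chloride channel, had a log2 fold change of 0.63 (SE 0.17). Agr2, a mucin folding factor, was at 9.11 and 6.43 CPM against 11.4 and 29.1 CPM (1.38, SE 0.44), with a log2 fold change of 0.57 without Smad4 Knockout 2. Clu (-0.18), Aqp5 (-0.17), Cd44 (-0.05) and Wfdc2 (-0.02) were the other members below 0. Squamous and forestomach markers were higher in 10 of 12 tested members with a median of 0.52 (camera adjusted p = 0.0276, and adjusted p = 0.551 with an estimated correlation). Krt4, a keratin of stratified epithelium, was at 116 and 89.9 CPM against 192 and 251 CPM (1.11, SE 0.18) and was the 1 member that rose adjusted over the list alone in edgeR and over all genes in DESeq2. Krt5 and Krt14 stayed under 1.2 CPM in all libraries, and Sprr1a had a log2 fold change of -0.35. The mucous neck list was not called without Control 2 (median 0.42, adjusted p = 0.0597) or Smad4 Knockout 2 (median 0.21, adjusted p = 0.0783), and its median was 1.06 without Control 1. The squamous list was not called when any of the libraries was left out (adjusted p = 0.0531 without Control 1, 0.0856 without Control 2, 0.0622 without Smad4 Knockout 1 and 0.183 without Smad4 Knockout 2), and its median was 0.34 without Control 1 and 0.83 without Control 2.

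Interferon-stimulated genes and antigen presentation genes were higher as lists. Of 20 tested interferon-stimulated genes 16 were higher, with a median log2 fold change of 0.40 (camera adjusted p = 0.00574, and adjusted p = 0.551 with an estimated correlation). Oas1a was at 2.56 and 1.03 CPM in the controls against 3.31 and 6.38 CPM in the knockouts. Rtp4 and Irf7 had log2 fold changes of 1.53 (SE 0.44) and 0.96 (SE 0.41, and 0.46 without Smad4 Knockout 2), and Usp18 one of -0.63. Adjusted over the list alone, 0 interferon-stimulated genes passed in edgeR, and over all genes 0 in DESeq2. Of 13 tested antigen presentation genes 9 were higher, with a median of 0.25 (camera adjusted p = 0.0129, and adjusted p = 0.551 with an estimated correlation). Tap1 and Tap2, the peptide transporter subunits, rose adjusted over the list alone, which is 2 members in edgeR against 0 over all genes, where DESeq2 called both. Tap1 was at 0.388 and 0.227 CPM against 1.48 and 2.85 CPM (2.81, SE 0.51), and Tap2 had a log2 fold change of 2.13 (SE 0.53). The abundant class I genes H2-K1 (-0.05), H2-D1 (0.03) and B2m (-0.08) lay near 0, with the H2 genes uncertain because their sequences are close. Neither list was called without Control 2 (adjusted p = 0.0574 and 0.239) or without Smad4 Knockout 2 (0.362 for both). The interferon median was 0.16 without Smad4 Knockout 2 and 0.64 without Smad4 Knockout 1. The antigen presentation median was 0.02 without Smad4 Knockout 2, 0.13 without Control 2, 0.43 without Control 1 and 0.66 without Smad4 Knockout 1.

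Cholesterol synthesis, NRF2 target and epithelial junction genes made up the remaining higher lists. Of 18 cholesterol synthesis genes 16 were higher, with a median log2 fold change of 0.17 (camera adjusted p = 3.5e-04, and adjusted p = 0.551 with an estimated correlation). Dhcr7, the last enzyme of cholesterol synthesis, was at 19.7 and 20.6 CPM in the controls against 30.2 and 30.7 CPM in the knockouts (0.60, SE 0.12), and was the 1 member that rose adjusted over the list alone in edgeR and over all genes in DESeq2. Idi1 had a log2 fold change of 0.37 (SE 0.13, and 0.24 without Smad4 Knockout 2). Of 15 NRF2 targets 12 were higher, with a median of 0.13 (camera adjusted p = 0.0267, and adjusted p = 0.551 with an estimated correlation). Gsta4, a glutathione transferase, was at 322 and 299 CPM against 364 and 523 CPM, Nqo1 had a log2 fold change of 0.39 (SE 0.17, and 0.24 without Control 1 or without Smad4 Knockout 2), and 0 members passed adjusted over the list alone in edgeR or over all genes in DESeq2. Of 22 epithelial junction genes 15 were higher, with a median of 0.05 (camera adjusted p = 0.0486, and adjusted p = 0.551 with an estimated correlation). Cdh17, which is also in the intestinal list, and Dsc2, a desmosomal cadherin at 40.1 and 41.5 CPM against 56.4 and 60.5 CPM, rose adjusted over the list alone in edgeR and over all genes in DESeq2. Cldn4 had a log2 fold change of -0.59 (SE 0.27), at 824 and 643 CPM against 616 and 357 CPM, lowest in Smad4 Knockout 2. The cholesterol list was not called without Control 2 (adjusted p = 0.0597) or Smad4 Knockout 2 (adjusted p = 0.104), each with a median of 0.11. The NRF2 list was not called without Control 1 (adjusted p = 0.274) or Smad4 Knockout 2 (median 0.07, adjusted p = 0.202). The junction list was not called without Control 2 (adjusted p = 0.313), Smad4 Knockout 1 (adjusted p = 0.303) or Smad4 Knockout 2 (median 0.08, adjusted p = 0.104), and its median was 0.03 without Control 1.

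**Figure D3:**
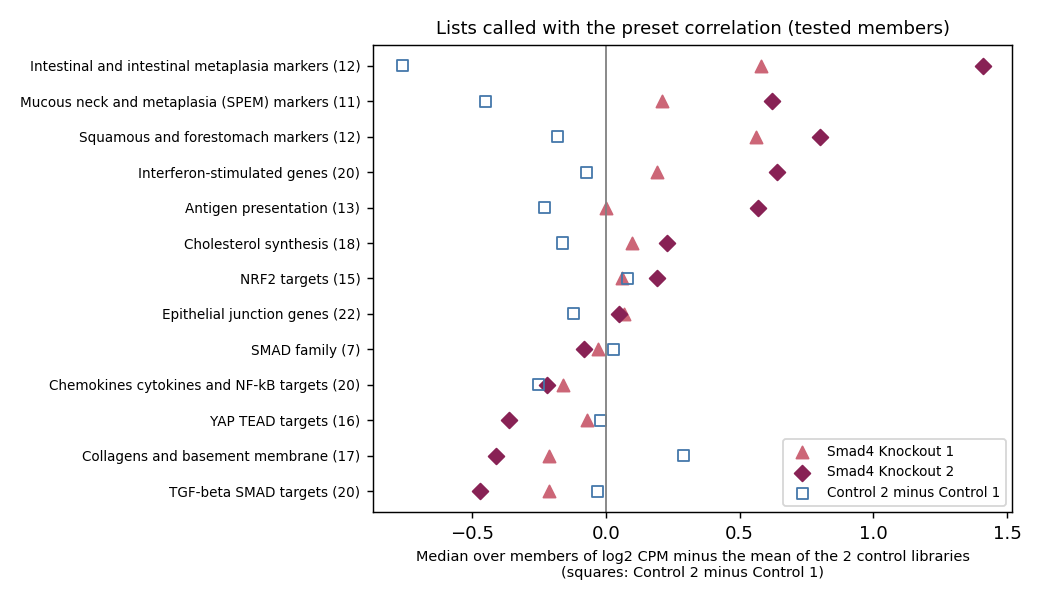
Median over the tested members of each called list of log2 CPM in a knockout library minus the mean of the 2 controls (triangles and diamonds), and of Control 2 minus Control 1 (open squares), on a log2 scale. In the intestinal list Smad4 Knockout 1 lies at 0.58, Smad4 Knockout 2 at 1.41 and the difference between the controls at -0.76.

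The other 17 tested lists were not called. BMP SMAD targets had a median log2 fold change of 0.05 and a mean of 0.04, with a camera direction of lower (adjusted p = 0.982). TGF-beta and BMP ligands and receptors had a median of 0.02 (0.502), mesenchymal and EMT genes of -0.27 (0.222), Notch pathway genes of -0.02 (0.317) and p53 targets of -0.08 (0.333), each with camera's adjusted p in parentheses. Wnt and beta-catenin targets had a median of -0.10 and a mean of 0.26, with a camera direction of higher (adjusted p = 0.502), and EGFR ligands and receptors a median of -0.07 and a mean of 0.06, with a direction of lower (0.853). Cell cycle and proliferation genes had a median of 0.08 with 20 of 25 above 0 (adjusted p = 0.0601, and called under 6 of the other settings tried), CDK inhibitors of -0.22 (0.206), glycolysis genes of -0.13 (0.0748) and unfolded protein and amino acid stress genes of -0.02 (0.568). Surface mucous markers had a median of 0.37 (0.0702), parietal cell markers of 0.45 (0.0606), tuft cell markers of 0.15 (0.502) and gastric transcription factors of 0.11 (0.357). Adjusted over the list alone, 0 members of these lists passed in edgeR, and over all genes DESeq2 called 2 surface mucous markers, Gkn1 and Tff1, as higher.

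Markers of other cell types were low. Of the immune markers (median 0.02, mean -0.20, camera direction lower, adjusted p = 0.524), Cd68 was the highest at 3.60 and 3.23 CPM in the controls and 3.46 and 3.79 CPM in the knockouts. Of the endothelial markers (median -0.38, adjusted p = 0.357), Kdr was the highest at 4.71 and 4.14 CPM against 3.96 and 2.83 CPM. The fibroblast list had 3 tested members, too few for the test, and all 3 were lower in both knockouts than in both controls (median -1.15). Pdgfra was at 1.54 and 1.68 CPM against 1.02 and 0.619 CPM (-0.98, and -0.65 without Smad4 Knockout 2), and Col1a1 at 0.89 and 1.53 CPM against 0.66 and 0.43 CPM. Chief cell markers had 2 tested members and enteroendocrine markers 3, with Tph1 at 2.85 to 3.19 CPM, and no erythroid marker was tested.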

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

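Protein-coding genes only, robust moderation, list tests without mitochondrial, ribosomal protein and histone genes, and the SMAD family list without Smad4 were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the replicate numbers only follow the order of the samples. The counts of 0 genes higher and 0 lower in edgeR (603 and 550 at an unadjusted p under 0.05) stayed at 0 with RLE size factors, no filter, a 2-fold minimum, limma on TPM, protein-coding genes only, robust moderation and without mitochondrial, ribosomal protein and histone genes. DESeq2 gave 99 higher and 34 lower, including Smad4 at -0.88, and the cause was not tested on these libraries. Its 152.2 false calls came from simulations with 200 changed genes. Leaving out a library gave from 0 to 48 genes higher and from 0 to 44 lower, the highest counts without Smad4 Knockout 1, where the lone knockout library is assumed to vary like the controls, and of these 36 and 7 were also DESeq2 calls. The 8 lists higher and 5 lower became 0 and 0 with an estimated correlation, a test on 2 residual degrees of freedom, and 0 and 0 with fry. Leaving out a library gave from 1 to 9 lists higher and from 1 to 4 lower, lowest without Smad4 Knockout 2, where 2 of the 13 called lists were kept, and without Control 2, where 5 were kept and 2 lists were higher. All 13 were kept with RLE size factors and without mitochondrial, ribosomal protein and histone genes, 11 with DESeq2 and with protein-coding genes only, and 10 with limma on TPM and with no filter. The chemokine list was lost under all 4 of these settings, the squamous list under DESeq2, limma and no filter, the junction list under no filter and protein-coding genes only, and the antigen presentation list under limma. Medians moved by over 1.5 times in the chemokine list (-0.03 with no filter and -0.04 with DESeq2), in the squamous list (0.27 with no filter and with DESeq2, and 0.12 with limma) and, with limma, in the collagen (-0.12), SMAD family (-0.03), junction (0.09) and antigen presentation (0.14) lists. Lists called only under an alternative were the cell cycle list (without Control 1, without Smad4 Knockout 1, with no filter, DESeq2 and limma, and without mitochondrial, ribosomal protein and histone genes), the glycolysis list (without Control 2 and with DESeq2), the surface mucous list (without Smad4 Knockout 1 and with DESeq2) and the parietal cell list (without Smad4 Knockout 1). Of 70 single genes followed across the settings, 25 passed in DESeq2 and 11 without Smad4 Knockout 1. The SMAD family list lost its call without Smad4, at a median of -0.01. Over the libraries left out, the log2 fold change ranged from -0.94 to -0.82 for Smad4, from 0.12 to 0.63 for Cdh1 and from -0.46 to 0.05 for Trp53, which turned its sign without Control 2, and the ranges of Smad2 (-0.12 to 0.01), Laptm5 (-1.20 to 1.23) and Flt1 (-0.02 to 0.55) also crossed 0; the cause was not tested. Depth does not limit genes above 5 CPM, but members under 1 CPM, such as Tap1 or Tff3 in the controls, rest on few counts.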

Other observations

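Some genes outside the lists were read in both libraries of one genotype and not in the other. With 0 counts in both controls and at least 20 counts in both knockouts, 23 genes were found, and 11 with the reverse pattern. Akr1c21, an aldo-keto reductase, had 39 and 94 counts in the knockouts, Cyp2d10, a cytochrome P450, had 37 and 39, and Slurp1, a secreted Ly6 family protein, had 23 and 45. Slc17a6, a vesicular glutamate transporter, had 55 and 35 counts in the controls, and Pyroxd2 had 26 and 38. The same count over the other pairings of the libraries gave 10 and 12 genes, and 8 and 15, so patterns of this kind also arise without the genotype. These genes were chosen after their values were seen. A 0 from a tool that assigns reads to transcripts can be a failed estimate, which was not tested. Within the gastric lists that were not called, Gkn1, a surface mucous secreted protein, was at 2.95 and 2.54 CPM in the controls and at 5.87 and 19.97 CPM in the knockouts, and Pdx1, a transcription factor of the antrum, was at 7.34 and 3.91 CPM against 8.57 and 24.2 CPM.

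The tests of depth or scaling, of a single knockout library, of mixed-in cells, of other splits and of whole chromosomes were chosen after the result was seen; those of the region around Smad4 and of RNA quality were not. Smad4 reads were lower in both knockout libraries, at 54.2% of the control level. Loss of the whole region would lower its neighbours, but the median log2 change of 16 tested genes within 2 Mb was -0.05 (SE 0.11), where a cause would put it at or below -0.44. Scaling does not account for it, since the fall kept a size of -0.76 or more under 4 other scalings. The genotype label names a Smad4 knockout without its extent. A candidate explanation is partial loss of the transcript from the knocked-out gene, which may leave reads from the remaining exons. Reads per exon were not analysed here, and whether every copy of the gene was changed in all cells was not tested.

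The TGF-beta target list was lower and the intestinal list higher in the knockouts. With the preset correlation, no single knockout library decided either call, since both lists were also called after either knockout library was left out. Without Smad4 Knockout 2 the medians were -0.21 in the TGF-beta list and 0.56 in the intestinal list. Without Smad4 Knockout 1 they were -0.48 and 1.48. Whether a single knockout library decides the result without that preset stays open. Without Smad4 Knockout 2 the larger adjusted p of both lists was 0.000743, but this rests on the preset correlation, and with the estimated correlation neither list is called even with all libraries (adjusted p = 0.551). Smad4 Knockout 2 lay further from the mean of the controls in both lists (median -0.47 against -0.21, and 1.41 against 0.58). Control 2 minus Control 1 had a median of -0.03 in the TGF-beta list and -0.76 in the intestinal list. That is the full difference between the controls, so it is not on the scale of values taken from their mean. In the intestinal list 7 of 12 tested members were higher in both knockouts than in both controls, and 0 were lower in both. Smad4 Knockout 2 also had the highest shares of mitochondrial counts (1.48%) and ribosomal RNA counts (0.562%), and RNA quality in that library was not tested for these lists. Absorptive enterocytes or Paneth cells mixed into the knockout cultures are argued against. The summed means of Fabp1, Fabp2, Guca2a, Lyz1 and Mep1a differed by 0.10 CPM, while the mean of Cdh17 was higher by 70.9 CPM. Goblet cells are argued against as the source of the 194 CPM by which the mean of Clca1 was higher in the knockouts. The summed means of the goblet cell genes Muc2, Spink4 and Tff3 were higher by 7.30 CPM. A small share of goblet or other intestinal cells stays open, since 3 of these 4 goblet cell genes were higher in both knockouts than in both controls, with Muc2 the exception. The 3 tested fibroblast markers, at most at 1.68 CPM, were lower in both knockouts (median -1.15). Mixed-in fibroblasts were not tested for either list. The 3 splits of the 4 libraries are too few for a share under 0.05; the real split called 13 lists and the highest other called 9, and that other split, Control 1 with Smad4 Knockout 2 against Control 2 with Smad4 Knockout 1, also called both lists (adjusted p = 0.0117 and 0.00403) and gave 340 DESeq2 genes against 133. The remaining split called 3 lists, with the TGF-beta list among them (adjusted p = 0.0475). That list was thus called in all 3 splits, with the smallest camera adjusted p in the real split (9.0e-09). A mixed split is not free of a genotype difference that is larger in 1 knockout library, and Smad4 Knockout 2 lay further out in both lists. The mixed splits therefore cannot decide whether these calls depend on the genotype. A candidate explanation is the genotype, with the Smad4 knockout lowering TGF-beta SMAD target genes. BMP SMAD targets were not called (6 of 12 tested members higher, median 0.05, camera adjusted p = 0.982). Differences between organoid lines may contribute. There were 2 lines per genotype, and no label says whether the Smad4 knockout lines were derived from the control lines. Genotype and line therefore cannot be told apart.

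The libraries did not group by genotype: Smad4 Knockout 1 was closer to both controls than to Smad4 Knockout 2, while Smad4 Knockout 2 was closest to Smad4 Knockout 1. Gain or loss of a whole chromosome in all cells of a line is argued against. The largest median deviation of a library on any autosome or the X chromosome was 0.141 on the log2 scale, for Control 2 on chromosome 1. A gain or loss in part of the cells would give a smaller deviation, and stays open. Leaving out 41 mitochondrial, ribosomal RNA and small noncoding genes kept the order of the distances, and the smallest distance between genotypes minus the largest within was -0.055. That test covers those genes, and an effect of RNA quality on messenger RNA stays open, as does variation between the lines themselves. No biological explanation was tested for this pattern.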
